A study of Mus musculus with 2 samples.

How the data were processed

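The data are the peak lists of 2 CUT&Tag libraries made with an antibody against RUNX2 in untreated MC3T3-E1 cells, as replicates of a single group. There is no control library and no other condition among the samples, so no background was subtracted here and no contrast between groups was made. Per the submitters' processing notes, the tools named are fastp 0.19.6, Bowtie2 and deepTools and the genome build is GRCm38 (mm10), without their roles or settings. The peak caller, its threshold and any use of a control are not given in the sources used here. The deposited lists have 5 columns without a header, which the values show to be a running number, the chromosome, the start, the end and the width of each peak. The width equals the end minus the start plus 1 in every line, so both ends were read as included and positions as counted from 1. The lists hold no score, height, summit or p-value, and the peaks were listed for each replicate on its own, not for pooled reads. Read numbers are not in the lists, so depth is unknown. Wilson intervals at the 95% level are given for shares of peaks, and they cover counting error only.

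Genes came from the RefSeq annotation of the same build (GRCm38.p6), as a table of gene spans with 49943 genes on chromosomes 1 to 19, X and Y, of which 21887 are protein-coding. This table holds no strand, exon or transcript, and no genome sequence was used. The plan fixed before the data were examined was changed accordingly. Peak width replaced the peak score for ranking and for the stricter threshold. The midpoint of the widest replicate 1 peak of a region replaced the summit. Either end of a gene replaced the transcript start, and 10 kb beyond either end replaced 10 kb upstream. Shares in exons and introns are not given, and the planned search for the RUNX motif was not run.

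Peaks of both lists that overlapped by at least 1 bp were merged, and a merged region holding peaks of both replicates is called a shared region. Counts of overlapping peaks were checked to equal those of bedtools 2.31.1. The overlap was compared with 1000 random placements of the replicate 2 peaks on the same chromosomes (one-sided permutation test). The position of shared regions relative to gene ends was compared with 1000 random placements on the same chromosomes (two-sided permutation test). Placement covered the span of each chromosome from its first to its last gene or peak and did not leave out stretches where reads cannot be mapped. A gene was linked to a region whose position lay inside it or within 10 kb of either end. A region can be linked to several genes, and the link shows position only, not regulation.

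For 18 gene lists with 333 memberships, fixed before the data were examined, the number of members with a shared region was compared with 10000 random lists of the same size matched on the decile of gene length (two-sided permutation test, Benjamini-Hochberg adjustment over the 18 lists, threshold 0.05). The smallest p this test can give is 2.0e-04, and the smallest printed adjusted values follow from it. The lists cover osteoblast matrix genes, osteoblast transcription factors, osteocyte genes, osteoclast support, BMP and TGF-beta, Wnt, FGF with hedgehog and PTH, chondrocyte, adipocyte, AP-1 and early response, actin cytoskeleton and YAP, fibroblast, cell cycle, ribosomal protein, neuron, liver, blood cell and skeletal muscle genes. The genes named in the text follow a rule fixed at the same time. Always named are Runx2, Sp7, Bglap, Spp1, Ibsp, Alpl, Col1a1 and Mmp13. From each list past the threshold come the 4 members, and from each other list the 2 members, whose best shared region had the highest mean rank of peak width over both replicates. Last come the genes nearest to the 10 widest shared regions by that mean rank. A gene that this rule selects is not reported here. Genes outside this rule are named as such, apart from Supt3, which is named because it overlaps Runx2.

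Tested on simulated data, with 100 sets of links drawn for the 21887 genes and an odds ratio of 10 planted in 9 of the lists, the list test called 79.6% of the planted lists and 0.56% of the 9 others. Smaller excesses in lists of this size would often be missed. Links were simulated for each gene on its own, so these rates do not cover list members that share a region. The alternatives tried were only the peaks wider than the median of their list, a reciprocal overlap of at least 50%, each replicate alone, positions from replicate 2, other distances and links to genes, protein-coding gene ends only, and only chromosomes 1 to 19, X and Y. Others were added after the data were seen. These were regions moved by 5 to 50 kb in place of random placement, only regions within 1 kb of a gene end, and random lists matched on gene density. Matching on gene density used coarser classes of gene length in place of the deciles. Also added were nearest-gene links for regions over 1 kb from any gene end, and nearest-gene links with random lists matched on the length of sequence nearest to each gene. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.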

Results

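RUNX2 binding was profiled by CUT&Tag in MC3T3-E1, a mouse cell line of osteoblast precursors that forms mineralised matrix in culture. RUNX2 is the Runt-family transcription factor required for osteoblast differentiation and bone formation. In CUT&Tag, an antibody against the protein directs the transposase Tn5 to its sites on chromatin, where the enzyme cuts the DNA and inserts sequencing adapters. The cells were untreated, and the series holds 1 group with 2 replicate libraries. The study's stated purpose was to find the transcriptional targets of RUNX2 across the genome. Each replicate has its own list of peaks, with 26853 peaks in replicate 1 and 27287 in replicate 2 (mean 27070 ± 306.88, SD, n = 2). The lists give the position and width of each peak and no height, so read depth is unknown and all comparisons rest on where peaks lay. The labels do not say whether the replicates came from separate cultures, and the spread between them may be technical.

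The widest regions found in both replicates lay beside genes of varied function. The region ranked first by mean rank of peak width over both replicates lay on chromosome 9 from 66988717 to 66991220 (GRCm38). It was 2279 bp wide in replicate 1 and 2490 bp in replicate 2. Its nearest protein-coding gene end was that of Lactb, 14597 bp away. Others in the top 10 lay across the high end of Tnrc18 (chromosome 5, 142821610 to 142823746), inside the platelet integrin gene Itga2b (chromosome 11, 102465762 to 102467645), at the low end of the ubiquitin gene Ubb (chromosome 11, 62549803 to 62551689) and 3261 bp beyond Wnt10a, which encodes a Wnt ligand (chromosome 1, 74806498 to 74808350). The remaining members were nearest to Gm20783, Hcfc1r1, Tcte2, Ppp1r13l and Usp5. The Gm20783 region was wider than the first in replicate 1, at 2835 bp, and narrower in replicate 2, at 1956 bp. In all, 18323 peaks of replicate 1 (68.2%, 95% Wilson interval 67.7 to 68.8) overlapped a peak of replicate 2, and 18327 peaks of replicate 2 (67.2%, 66.6 to 67.7) overlapped one of replicate 1. Merging these gave 18133 shared regions with a median width of 629 bp, of which 17758 were made of 1 peak from each list.

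The overlap was far above random placement. On chromosomes 1 to 19, X and Y, 18318 peaks of replicate 1 were overlapped, against a mean of 276.3 and a maximum of 324 over 1000 random placements of the replicate 2 peaks on the same chromosomes (ratio 66.3, one-sided permutation p = 0.001, the smallest these placements can give). With each replicate 2 peak moved by 5 to 50 kb in place of random placement, an alternative chosen after the data were seen, the mean was 638.1 and the ratio 28.7. Wider peaks were shared more often. In replicate 1 the shared part rose from 36.0% (34.7 to 37.3) in the narrowest of 5 width classes of about equal size, with widths of 163 to 236 bp, to 96.5% (96.0 to 96.9) in the widest, and in replicate 2 from 33.2% (32.0 to 34.5) to 96.3% (95.7 to 96.7). Peaks of a single replicate numbered 8530 in replicate 1 and 8960 in replicate 2. Only 23 peaks had identical start and end in both lists, so the lists are not copies of each other.

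**Figure D1:**
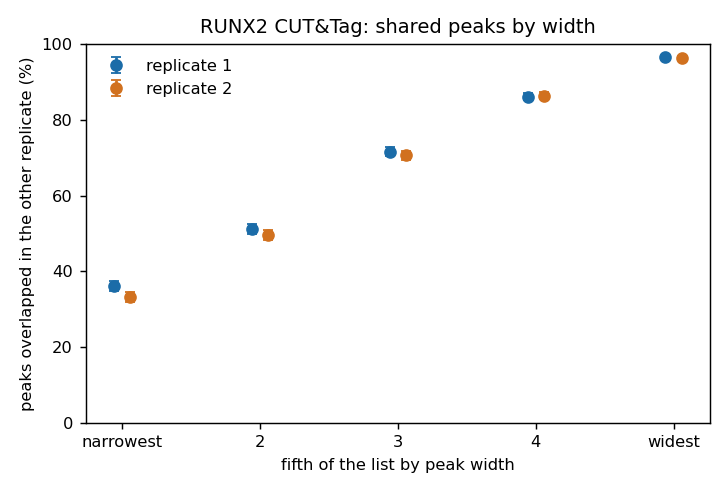
Share of peaks overlapped by a peak of the other replicate (%, vertical axis) in 5 classes of peak width of about equal size (horizontal axis), in replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. The share rises from 36.0% and 33.2% in the narrowest class to 96.5% and 96.3% in the widest.

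Shared regions were concentrated at the ends of genes, and most of them nevertheless lay farther away. Of the 18128 shared regions on chromosomes 1 to 19, X and Y, 6936 (38.3%, 95% Wilson interval 37.6 to 39.0) lay within 1 kb of the end of an annotated gene, for example at Egr1, Vim and Dusp6. Another 6819 (37.6%, 36.9 to 38.3) lay inside genes over 1 kb from any gene end, such as the 6 regions inside Tgfbr3, which encodes the TGF-beta coreceptor betaglycan. The other 4373 (24.1%, 23.5 to 24.8) lay outside genes. Random placement on the same chromosomes put 6.4% near a gene end (5.9 to 6.9 over 1000 placements), 45.0% inside genes and 48.6% outside them. The observed shares were 5.95, 0.84 and 0.50 times these (two-sided permutation p = 0.002 for each, the smallest possible). The ratio near gene ends was 3.8 with regions moved by 5 to 50 kb, chosen after the data were seen, 2.98 with a limit of 3 kb and 10.49 with protein-coding gene ends only. The median distance to the nearest gene end was 3454 bp, against 16654 bp for random positions. Over all peaks, whether shared or not, 32.03% ± 0.30 (SD, n = 2) lay within 1 kb of a gene end. Either end of a gene counted, because the annotation used gives no strand, and starts and ends of transcription could not be separated.

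**Figure D2:**
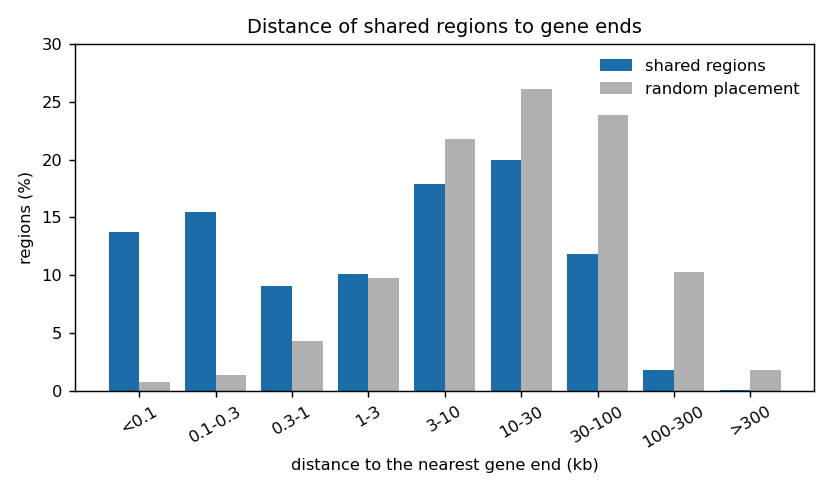
Percent of shared regions (blue) and of the same regions placed at random on their chromosomes (grey) by distance to the nearest gene end in kb, in classes of increasing width. Shared regions exceed random placement in the 3 classes under 1 kb, and random placement exceeds them beyond 3 kb.

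Among 8 genes known as RUNX2 targets or osteoblast markers, Runx2, Spp1, Col1a1 and Sp7 were linked to shared regions, and Bglap, Ibsp, Alpl and Mmp13 were not. A gene was linked to a region lying inside it or within 10 kb of either end. Of all protein-coding genes, 52.7% were linked in this way, so these links on their own show no excess. Runx2 itself (chromosome 17, 44495987 to 44814797) had 7 shared regions. One, from 44814595 to 44815136, covered the gene's high end, and another, from 44776884 to 44777610, lay inside Runx2 at the low end of the overlapping gene Supt3. The other 5 lay inside Runx2 over 1 kb from any gene end. Spp1, which encodes the bone matrix protein osteopontin (chromosome 5, 104435111 to 104441053), had 2 regions, of which one (104434604 to 104435335) had its midpoint 241 bp outside the low end. Col1a1, which encodes the main chain of type I collagen (chromosome 11, 94936224 to 94953042), had one region 7417 bp below its low end, near the end of another gene, and one 5120 bp above its high end. Sp7, which encodes the osteoblast factor osterix (chromosome 15, 102356603 to 102367035), had a single region 5677 bp below its low end, which was also near the end of another gene. The shared region nearest to Bglap, the osteocalcin gene, was 25.7 kb away. Those nearest to Ibsp, which encodes bone sialoprotein, to the alkaline phosphatase gene Alpl and to the collagenase gene Mmp13 were 33.3, 57.6 and 88.1 kb away. Alpl had 1 peak in each replicate, at different places. The lists contain only called peaks, and a gene without one may still carry signal below the calling limit.

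**Figure D3:**
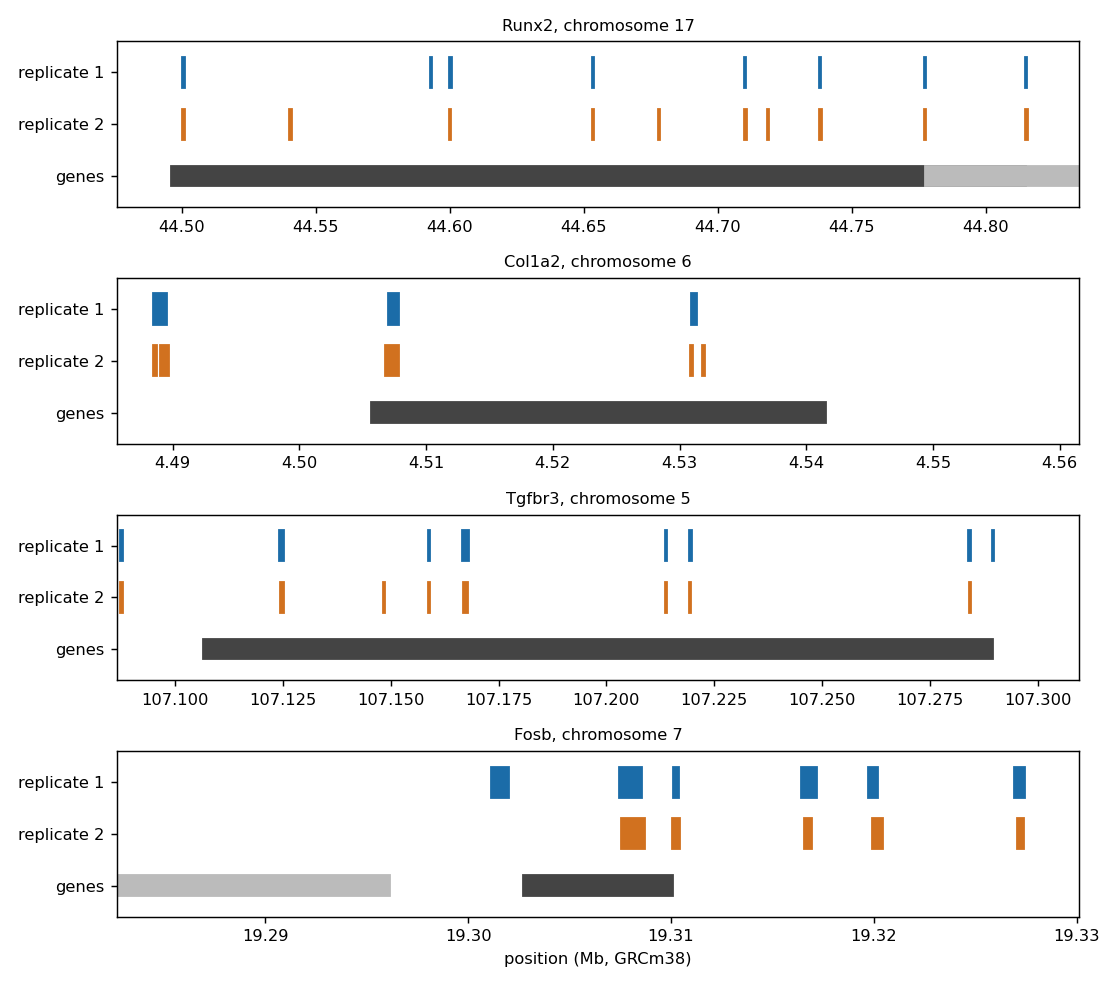
Peaks of replicate 1 (blue) and replicate 2 (orange) at Runx2, Col1a2, Tgfbr3 and Fosb with 20 kb to either side, to scale by position (Mb, GRCm38) except that the narrowest peaks are drawn at a minimum width. The named gene is dark grey and other protein-coding genes are light grey. Shared regions within 10 kb of the gene number 7 at Runx2, 2 at Col1a2, 6 at Tgfbr3 and 4 at Fosb.

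AP-1 and early response genes, genes of the actin cytoskeleton and YAP pathway, and ribosomal protein genes were linked to shared regions more often than matched random lists. All 18 AP-1 and early response genes had a region, against 8.0 expected (95% range of the random lists 4 to 12, adjusted permutation p = 0.0018). They included Egr1, a zinc finger factor induced by growth factors, whose region from 34859847 to 34861383 on chromosome 18 was 1537 bp wide in replicate 1 and 1470 bp in replicate 2. Fosb, which encodes an AP-1 subunit, had 4 regions, Ier3 had 3, and Egr2 had 2. In the cytoskeleton and YAP list, 16 of 18 genes had a region against 10.2 expected (6 to 14, adjusted permutation p = 0.03). Wwtr1, which encodes the YAP paralogue TAZ, had 6 regions, its partner Tead1 had 4, and the YAP targets Ankrd1 and Amotl2 had 2 and 1. In the ribosomal protein list, 19 of 22 genes had a region against 9.6 expected (5 to 14, adjusted permutation p = 0.0018), and Rpl7, Rpl23 and Rpl3 had 1 each, all within 1 kb of an end of the gene.

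The AP-1 and the cytoskeleton and YAP genes were above matched lists both near gene ends and away from them, and the ribosomal protein genes near gene ends. With only regions within 1 kb of a gene end, an alternative chosen after the data were seen, the counts were 16 against 6.9 for AP-1 (adjusted permutation p = 0.0018), 15 against 7.8 for the cytoskeleton and YAP list (adjusted permutation p = 0.0072) and 19 against 8.4 for ribosomal protein genes (adjusted permutation p = 0.0018). With only regions over 1 kb from any gene end, the AP-1 list had 11 linked genes against 2.2 expected (adjusted permutation p = 0.0036) and the cytoskeleton and YAP list 12 against 4.5 (adjusted permutation p = 0.0036). The fibroblast and mesenchymal list then also passed the threshold, with 10 of 17 genes against 4.7 (adjusted permutation p = 0.043), and the ribosomal protein list had 2 against 2.3 (adjusted permutation p = 1.0). Of the 25 regions linked to ribosomal protein genes, 92.0% (95% Wilson interval 75 to 97.8) were near a gene end, a share that differed from that of all other shared regions (two-sided Fisher's exact test, adjusted p = 5.4e-07 over 18 lists). For the 22 regions of cell cycle genes it was 90.9% (72.2 to 97.5, adjusted p of the exact test = 3.7e-06), and no other list passed the threshold in this comparison. The comparison was chosen after the data were seen and did not set the lists against each other. It matched neither gene length nor gene density, and it counted regions of the same gene as independent. With only the peaks wider than the median of their list, the cytoskeleton and YAP list (11 genes against 7.0, adjusted permutation p = 0.358) and the ribosomal protein list (12 against 6.5, adjusted permutation p = 0.114) lost their calls. Of 13 alternatives, 5 of them chosen after the data were seen, the AP-1 list passed under 13 (adjusted permutation p from 7.2e-04 to 0.0036), the cytoskeleton and YAP list under 12 (7.2e-04 to 0.358) and the ribosomal protein list under 9 (0.0012 to 1.0).

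Liver, skeletal muscle and blood cell genes were linked to shared regions less often than matched lists. Of 14 liver genes, Fgb, a fibrinogen gene, was the 1 with a region, against 8.0 expected (4 to 11, adjusted permutation p = 0.0024), and that region was 5597 bp from Fgb and near the end of another gene. Of 13 muscle genes, the myoglobin gene Mb, with 4 regions, and the troponin gene Tnnc2, with 2, were linked, against 6.8 expected (3 to 10, adjusted permutation p = 0.034). Of 16 blood cell genes, the 3 linked were the erythroid factor gene Klf1, the B cell receptor gene Cd79a and the T cell coreceptor gene Cd4, against 8.0 expected (4 to 12, adjusted permutation p = 0.045). All these muscle and blood cell regions lay nearer to the end of another protein-coding gene. Given the nearest gene end within 100 kb, muscle genes were at 0 against 5.6 expected and blood cell genes at 0 against 6.5 (adjusted permutation p = 0.003 and 0.0029). Neuron genes were at 5 of 16 against 9.4, which did not pass the threshold (adjusted permutation p = 0.112), with 1 region each at Camk2a and Syt1. With the peaks of replicate 2 alone, neuron genes did pass, at 6 against 10.9 (adjusted permutation p = 0.046), and with those of replicate 1 alone they were at 8 against 10.8 (adjusted permutation p = 0.338). With either replicate alone the liver list was at 4 against 9.2 and still passed. Of the 13 alternatives, the liver list passed under 10 (adjusted permutation p from 0.0018 to 0.315), the muscle list under 7 (0.003 to 0.556) and the blood list under 7 (0.0029 to 0.556). With only regions over 1 kb from any gene end the counts were 0 against 3.1 for liver, 1 against 2.6 for muscle and 1 against 2.9 for blood, where the range of the random lists reached 0 and a deficit could hardly pass.

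The osteoblast, osteocyte and osteoclast support lists did not pass the threshold under the main link, and the calls depended on how regions were given to genes. In the main comparison, 14 of 23 osteoblast matrix genes were linked against 12.8 expected (adjusted permutation p = 0.908), with 2 regions at Col1a2, which encodes the second chain of type I collagen, and 2 at Mgp, an inhibitor of calcification. Of 20 osteoblast transcription factors, 10 were linked against 10.6 (adjusted permutation p = 1.0), Atf4 having 1 region and Six2 having 2. The counts were 8 of 11 osteocyte genes against 6.2 (adjusted permutation p = 0.601), with 2 regions each at Dmp1 and Pdpn, and 10 of 14 osteoclast support genes against 7.7 (adjusted permutation p = 0.568), with the cytokine gene Il6 at 1 and the protease inhibitor gene Timp1 at 2. With each region given to the nearest protein-coding gene end within 100 kb, an alternative chosen before the data were examined, 16 osteoblast transcription factors were linked against 9.0 expected (adjusted permutation p = 0.0029) and 12 osteoclast support genes against 6.2 (adjusted permutation p = 0.0081). The matrix and osteocyte lists did not pass under that link (16 against 11.0, adjusted permutation p = 0.071, and 8 against 5.3, adjusted permutation p = 0.208). When this link was used with only regions over 1 kb from any gene end, chosen after the data were seen, all 4 lists passed (matrix 13 against 6.4, transcription factors 13 against 5.3, osteocyte 8 against 3.1, osteoclast support 10 against 2.6), and all but the osteocyte list (8 against 4.0, adjusted permutation p = 0.065) passed against lists matched on the length nearest to each gene. Of the 13 alternatives, the transcription factors and the osteoclast support genes passed under 4 each (adjusted permutation p from 7.2e-04 to 1.0 for both), the matrix genes under 2 (0.0099 to 1.0) and the osteocyte genes under 1 (0.0057 to 1.0). Pooled, 32 of 54 matrix, transcription factor and osteocyte genes were linked in the main comparison (59.3%). The neuron, liver, blood cell and muscle lists pooled had 11 of 59 (18.6%), and all protein-coding genes 52.7%. With only regions over 1 kb from any gene end, these shares were 42.6%, 10.2% and 22.7%. This pooling was not planned and did not match gene length.

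The signalling, other mesenchymal and cell cycle lists did not pass the threshold under the main link either. BMP and TGF-beta genes were at 20 of 29 against 16.8 (adjusted permutation p = 0.568), with 6 regions at Tgfbr3 and 3 at Id1, a BMP target. With the peaks of replicate 1 alone this list did pass, at 26 against 19.4 (adjusted permutation p = 0.024), and with those of replicate 2 alone it did not, at 24 against 19.5 (adjusted permutation p = 0.134). Wnt genes were at 21 of 35 against 20.6 (adjusted permutation p = 1.0), with 6 regions at Tcf7l2, which encodes a nuclear effector of the pathway, and 2 at the coreceptor gene Lrp5. The FGF, hedgehog and PTH list was at 11 of 16 against 9.5 (adjusted permutation p = 0.773), with 2 regions at Fgf2 and 1 at Dusp6. Chondrocyte genes were at 7 of 16 against 9.4 (adjusted permutation p = 0.568), with 9 regions inside the long gene Sox5 and 1 in Col2a1, and adipocyte genes at 8 of 14 against 7.5 (adjusted permutation p = 1.0), with 3 at Pparg and 2 at Fasn. Fibroblast and mesenchymal genes were at 12 of 17 against 9.9 (adjusted permutation p = 0.601), with 2 regions each at Vim and S100a4, and cell cycle genes at 16 of 21 against 11.7 (adjusted permutation p = 0.204), with 3 at Pcna and 1 at Mcm7. Given the nearest gene end within 100 kb, the BMP and TGF-beta list (21 against 14.8, adjusted permutation p = 0.047), the fibroblast and mesenchymal list (14 against 8.6, adjusted permutation p = 0.018) and the cell cycle list (15 against 9.5, adjusted permutation p = 0.047) passed as well. Of the 13 alternatives, the BMP and TGF-beta list and the fibroblast list passed under 5 each (adjusted permutation p from 0.0018 to 0.635 and from 7.2e-04 to 1.0), the cell cycle list under 3 (0.019 to 1.0), the FGF, hedgehog and PTH list under 2 (0.012 to 1.0), the Wnt list under 1 (0.044 to 1.0), and the chondrocyte and adipocyte lists under 0 (0.134 to 1.0 and 0.416 to 1.0). Across the genome 11525 of 21887 protein-coding genes (52.7%) were linked to a shared region, 6859 of them to exactly 1 and 297 to at least 5. A list that missed the threshold is not shown to equal random lists.

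**Figure D4:**
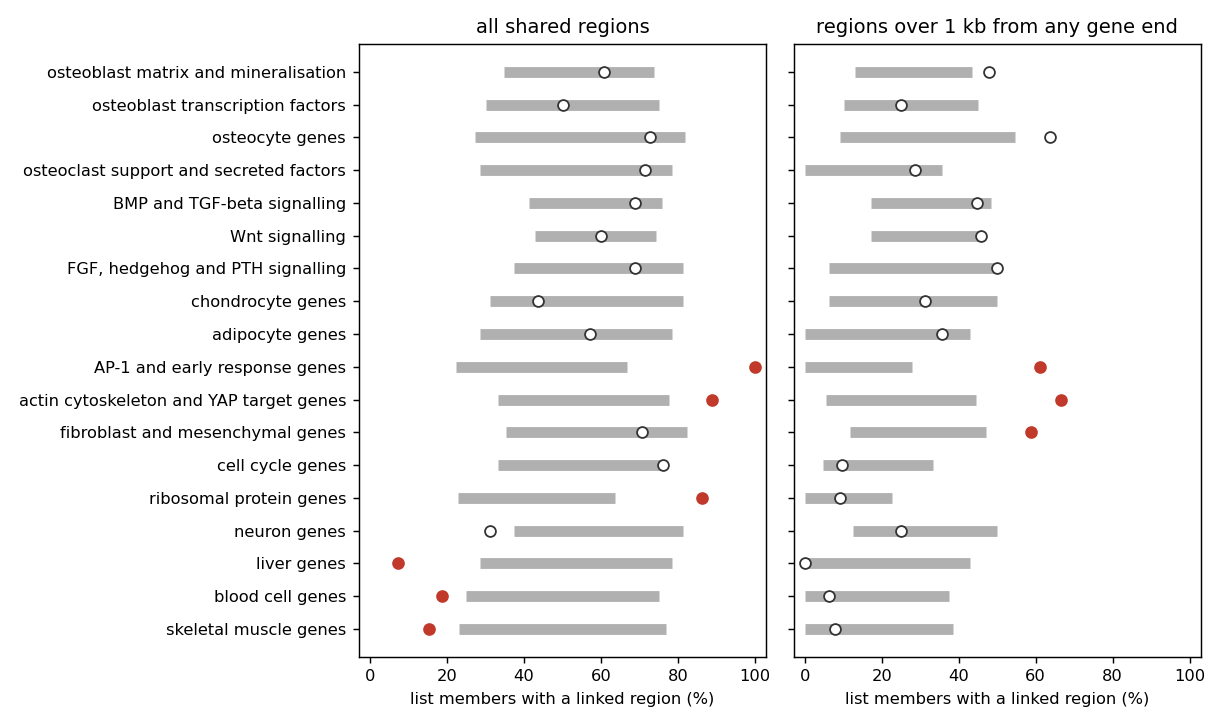
Percent of the members of each gene list with a linked region (circles, horizontal axis), for all shared regions (left) and for those over 1 kb from any gene end (right), with the 95% range of 10000 random lists matched on gene length as grey bars. Filled red circles have an adjusted p under 0.05: 6 lists on the left, 3 above and 3 below, and 3 lists on the right, all above.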

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

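The tests of broadly active genes, of weak sites and of chromosome X in this part, and the nearest-gene counts for regions over 1 kb from any gene end, were chosen only after the result was seen. Peaks outside chromosomes 1 to 19, X and Y numbered 7 in replicate 1 and 5 in replicate 2, and 4 and 3 of these lay on the unplaced sequence JH584304. Both counts were above 3, the limit used to flag them, which is the most that a count of 0 allows. That limit is not an expected number for these sequences, so no excess is shown. No control sample was used for comparison.

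For the gene lists above and below matched lists, signal at the ends of broadly active genes, which open chromatin alone could give in CUT&Tag, is a candidate explanation. Linked to a region within 1 kb of a gene end were 19 ribosomal protein genes against 8.4 expected (adjusted permutation p = 0.0018). This list was itself among those above matched lists, so its count describes the pattern and does not test the cause. It says nothing of the lists below matched lists. As the whole cause, signal within 1 kb of annotated gene ends is argued against by the AP-1 and the cytoskeleton lists. Both (2 lists) were still above matched lists with only regions over 1 kb from any gene end. The annotation holds no transcripts, so such regions may still lie at transcript starts inside genes, and signal there stays open. The result concerns gene ends only, and open chromatin away from them was not tested and stays open. A further explanation, that ends of neighbouring genes inside the flanks hide the osteoblast lists, predicted at least 1 of the 3 osteoblast and osteocyte lists above lists matched on gene density, and 0 were. This stays open, because a missed threshold in lists this small excludes nothing. The ratio rose from 1.10 to 1.29 for matrix genes and from 1.29 to 1.58 for osteocyte genes, and it stayed at 0.94 for transcription factors. With the same matching the ribosomal protein list was at 19 against 12.8 expected (adjusted permutation p = 0.026). Its ratio fell from 1.98 to 1.48, while those of the AP-1 and the cytoskeleton lists rose from 2.24 to 2.46 and from 1.57 to 1.67. Gene length was matched more coarsely there than by decile, so these changes cannot be put down to density alone. With regions over 1 kb from any gene end given to the nearest gene, 2 of the 3 osteoblast and osteocyte lists passed against lists matched on the length nearest to each gene (matrix 13 against 6.9, transcription factors 13 against 7.0). Osteocyte genes at 8 against 4.0 did not (adjusted permutation p = 0.065). How much of the signal, at gene ends or away from them, is RUNX2 binding and how much is open chromatin stays open without a control library. No biological explanation was tested because the series has a single group.

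Peaks found in 1 replicate only made up 8530 and 8960 of the lists. Calls spread evenly over the chromosomes as the whole cause are argued against by position: 19.1% of those in replicate 1 and 18.5% in replicate 2 lay within 1 kb of a gene end, against a maximum of 7.0% over 200 random placements. False calls gathered near gene ends could not be told apart in this way and stay open. Weak sites close to the calling limit stay open: the median width of these peaks was at most 0.53 of that of shared peaks, which follows from the lower sharing of narrow peaks and decides nothing. These peaks were near gene ends less often than shared peaks of the same widths (31.9% and 31.3%), so random calls as a part of them also stay open. No biological explanation was tested.

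Chromosome X held few shared regions, at 1.69 per Mb against 4.36 to 12.50 on the autosomes. Few genes on X are argued against as the cause, since X had 0.30 shared regions per protein-coding gene and the lowest autosome, chromosome 7, had 0.53. Lower signal on X stays open: 57.5% (95% Wilson interval 53.2 to 61.7) and 58.7% (54.3 to 63.0) of its peaks were shared, against 62.9% and 60.8% on the lowest autosomes, the second of which lies within the interval. The median width of regions near gene ends, 464 bp in replicate 1, equalled the lowest of the autosomes (464 to 606 bp). That lowest autosome was chromosome 13, which had 0.86 regions per gene. The copy number and the mappability of X were not tested and stay open, and no biological explanation was tested.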

How the results depend on the processing

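The settings with only regions within 1 kb of a gene end, those that combine the nearest gene with regions over 1 kb away, those matched on the length nearest to each gene or on gene density, and moves by 5 to 50 kb were chosen after the data were seen, as was the count of genes linked to regions over 1 kb away. The planned motif search and its alternatives were not run, and leaving out a replicate gives no value for shared regions. No paired analysis was possible because the series has a single group. The share of regions near a gene end stayed above random placement under all 8 alternatives (31.8% to 48.4%, permutation p = 0.002 each), and was 38.3% against 10.1% with moves by 5 to 50 kb. With only the peaks wider than the median of their list, 13409 and 13643 peaks and 9323 shared regions remained by construction, and 2 lists were called, AP-1 and liver. Genes with a shared region numbered 4970 with only regions over 1 kb from any gene end and 5266 when those were given to the nearest gene. Lists called numbered 11 with the nearest gene end, 3 with only regions over 1 kb away, 10 with those given to the nearest gene (8 against lists matched on the length nearest to each gene), and 11 with the nearest gene end and lists so matched, against 6 in the main setting and 7 without replicate 1 (neuron genes gained, 6 against 10.9, with 8 against 10.8 without replicate 2) and without replicate 2 (BMP and TGF-beta genes gained, 26 against 19.4). Osteoblast transcription factors went from chance level (10 against 10.6) to a call above it, with 16 linked by the nearest gene end (9.0 expected), 13 by the nearest gene for regions over 1 kb away (5.3 expected), and counts of 16 (adjusted permutation p = 0.019) and 13 (7.0 expected, adjusted permutation p = 0.024) with lists matched on the length nearest to each gene. Ribosomal protein genes lost their call at regions over 1 kb away and were at chance level, with 2 against 2.3 expected (adjusted permutation p = 1.0), and 3 against 2.6 by the nearest gene. The cause was not tested. Of the 60 named genes, the number of linked regions moved in 0 with positions from replicate 2 and in up to 36 with only regions over 1 kb away. Unknown depth limits what a missing peak can show.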

Other observations

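All comparisons in this part were chosen after the data were seen. Protein-coding genes were also grouped by the letters that start their symbols, which can join relatives of different function. Of 163 families with at least 15 members, 23 were linked to shared regions more often than matched lists and 34 less often (two-sided permutation test, Benjamini-Hochberg adjustment over the families). With lists matched on gene density, and on gene length more coarsely, 19 of the 23 and 25 of the 34 kept their call. In all, 21 were above and 30 below. The families named here kept theirs under that matching. Olfactory receptor genes (Olfr) were at 23 of 1110 against 191.6 expected and vomeronasal receptor genes (Vmn) at 10 of 355 against 111.0, both with adjusted permutation p = 0.0014. Cytochrome P450 genes (Cyp) were at 18 of 99 against 57.4, keratin genes (Krt) at 7 of 53 against 27.0, and major urinary protein genes (Mup) at 0 of 24 against 10.5, each with adjusted permutation p = 0.0014. Above matched lists were mitochondrial ribosomal protein genes (Mrpl, 42 of 49 against 23.5), translation initiation factors and their partners (Eif, 49 of 56 against 31.6), RNA polymerase subunits (Polr, 26 of 28 against 14.8) and Rab GTPases and their partners (Rab, 57 of 69 against 40.8), each with adjusted permutation p = 0.0014. With only regions over 1 kb from any gene end, 1 family was above and 4 were below, and Olfr, Vmn and Cyp were the named families that passed (adjusted permutation p = 0.011 each). Where genes of a family lie in arrays and share regions, its p-values are too small, and how far this holds for each family was not measured.

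Some genes were the nearest gene of many shared regions. Tns3, which encodes a tensin of focal adhesions, was the nearest gene of 16 shared regions, followed by Fndc3b and Irf2bp2 with 12 each. Ctif, Nfatc2, Plekha5 and 1600014C23Rik had 11 each, and Smad3, Col5a1, Cald1 and Tomm20 had 10 each. Tnfsf11, which encodes the osteoclast factor RANKL, had 0 shared regions within 10 kb and was the nearest gene of 6. These genes were named after their values were seen, and no test was made.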
